A study of Botryllus schlosseri with 10 samples.

How the data were processed

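Gene expression was measured in single cells of Botryllus schlosseri in 10 libraries, 8 of buds and 2 of circulating cells. Per the labels' protocols, bud cells were dissected with tunic and some ampullae, freed of tunic, dissociated with trypsin, fixed with the ACME method and sorted for single cells by a nuclear stain. Circulating cells were collected live and passed through a filter, and are not said to be sorted. The deposited values are counts of unique molecular identifiers (UMIs) per gene and barcode. Per the submitters' processing notes, the authors used FastQC and the Cell Ranger pipeline in versions 7.1.0 and 6.1.2; per the file headers, the bud count matrices were written by version 7.1.0, and the circulating matrices name no version. The bud matrices hold barcodes the authors' pipeline had kept, and the circulating matrices are raw, with 872198 barcodes at stage A1 and 1756503 at B2. The genome build and annotation are not given in the sources used here. Gene names were taken from the deposited feature tables, where 8235 of 22289 features carry a name, and how the names were given is not stated. The reference gene table did not share identifiers with these files and was not used.

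The libraries were grouped by material and by the developmental stage field. The titles of 2 bud libraries exchange stages B1 and B2 against that field; the library codes in their titles go with the field, which was used, and the exchange was an alternative. The stage order ran from A1 as 1 to C2 as 6, with 2 libraries at B2, and left out stage D, whose library held secondary buds only. Bud library codes, taken from the labels, were ML231, ML232 (3 libraries), ML245 (2 libraries), ML263 and ML275, so code and stage are largely confounded, as are material, fixation, genotype, sorting and matrix type.

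Bud barcodes were kept with at least 500 UMIs and 200 genes. Circulating barcodes needed 1/10 of the 99th percentile of the top 5000 barcodes. Doublets were scored by neighbours among simulated doublets in 20 principal components, with a threshold by Otsu's method; in the circulating stage B2 library this took over 20% of barcodes, and the top 5% was used instead. Depth and cell numbers per library are given with the results. Cells were normalised, 2000 variable genes and 30 principal components taken, and clustered with 15 neighbours and the Leiden method at resolution 1 with seed 1, buds and circulating cells apart. Circulating clustering used non-doublet barcodes of 500 to 100000 UMIs, and shares are over those past the UMI minimum. A marker had a UMI in at least 10% of a cluster's cells and a fold of at least 2 over the other cells. A cluster named "like" a tissue had at least 3 markers of its list; not every cluster with 3 was named, and no label gives cell types.

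Counts of kept cells were summed per library. Genes were filtered with filterByExpr, scaled with TMM and tested two-sided with edgeR's robust quasi-likelihood F test, with p-values adjusted by Benjamini and Hochberg at 0.05. Standard errors are the log2 fold change over the root of F. Levels (CPM) are counts scaled to a common total from the summed counts of all kept cells. Comparisons were circulating against bud libraries (2 against 8), the bud stage letters A (2 libraries), B (3), C (2) and D (1) in a joint fit, where a D contrast was not tested, and a slope over 7 bud libraries. The same slope was fitted within clusters having at least 20 cells in each of the 7 libraries. Cluster shares were related to stage order by Spearman's rho and Pearson's r with two-sided exact permutation over 5040 pairings, 53 relations each, adjusted by Benjamini and Hochberg. Circulating stages A1 and B2, and stage D against the other buds, have 1 library on a side and were compared as values with Poisson or exact Clopper-Pearson 95% intervals.

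Before the data were examined, 21 gene lists were written from general knowledge: muscle, heart and mesoderm, neural, cilia, endostyle and pharynx, digestive, epidermis and tunic, bud patterning, stemness and dedifferentiation, germline, pigment cell and phenoloxidase, blood cell and immune, phagocyte and lysosome, vessel and extracellular matrix, S phase, mitosis, dissociation stress, apoptosis, ribosomal protein, oxidative phosphorylation, and translation and nucleolus. The 19 with at least 5 tested members were tested with camera at an inter-gene correlation of 0.01, again with an estimated correlation, and with fry; heart and mesoderm, and pigment cell and phenoloxidase, had fewer. Named genes were the 10 largest rises and falls among named genes that passed, with a mean of at least 20 CPM in the higher group and no overlap between groups, and up to 4 members of each list with the smallest p. For untested comparisons they were the 10 largest ratios each way with at least 50 counts in the higher library and intervals that do not overlap, and for clusters the 3 named genes of largest fold. List members named as markers of a cluster were picked from its markers after these were seen. Some genes that the rule names are not reported here.

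Alternatives set before the data were examined were DESeq2 size factors, the DESeq2 Wald test, no low-count filter, each library left out, at least 1000 UMIs, doublets kept, equal weight per cell, circulating barcodes from 500 UMIs, bud stages A1 and B2 only, no stage D, B1 and B2 exchanged, D as last stage, letter order, D out of the letter fit, values within code ML232, resolution 0.5, genes centred per library, and the estimated correlation. Chosen after seeing the data were: without clusters of low depth, without barcodes over 100000 UMIs, the slope without ML232, library code as a block in the slope and in B against A, and 4 alternatives for the circulating stages. Where leaving out a library left a stage letter with 1 library, it was assumed to vary like the others.

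Tested on simulated data, the fit of circulating against bud libraries recovered 6 of 67 genes changed by 1 log2 unit, 31 of 67 changed by 2 and 64 of 66 changed by 4, with 7 false calls of 108. The slope fit recovered 1, 19 and 60 genes of the same sizes, where the change is over the whole order. The share test called 5 of 5 changed clusters of 40 and none of the others. Its simulated change was a large steady rise over the whole order without effects of library code, so smaller changes were not covered. Tools were Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.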

Results

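Botryllus schlosseri is a colonial tunicate that renews its zooids by budding, and the series was designed as a cell atlas of the buds and the blood over successive colony stages. Single-cell RNA libraries were made from 2 materials. The 8 bud libraries held fixed and sorted cells of 1 isogenic clone. They covered colony stages A1, A2, B1, C1, C2 and D with 1 library each and stage B2 with 2 libraries, and the stage D library held secondary buds only, while the others held primary and secondary buds. The 2 circulating libraries held live blood cells, from 5 pooled clones at stage A1 and from 6 pooled clones at stage B2. Libraries of a group were not stated to come from separate animals or cultures, so the p-values below measure only the spread between these samples.

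The unit of measurement was the unique molecular identifier (UMI) count per gene and barcode, over 22289 features of which 8235 carried a gene name. Total counts of the bud libraries were 66267639 UMIs at stage A1, 45233232 at A2, 61179241 at B1, 22620183 and 57675845 at B2, 36952329 at C1, 17300822 at C2 and 129221321 at D. The circulating libraries held 36115745 UMIs at stage A1 and 45961267 at stage B2. After filtering, 9685 cells remained at A1, 6306 at A2, 8200 at B1, 6973 and 8276 at B2, 7871 at C1, 4057 at C2 and 18420 at D, with 1329 and 911 circulating barcodes at A1 and B2, of which 38 at B2 exceeded 100000 UMIs and entered no cluster. The median depth of the kept bud cells ranged from 2314 UMIs in the first stage B2 library to 5486 at B1. Circulating barcodes past their much higher UMI minimum had medians of 14388 and 15448 before doublets were removed. Genes are named as the deposited feature tables name them, with a suffix number for each copy, and no coordinates were used.

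The bud cells fell into 53 clusters, several of which expressed the markers of a tissue. Cluster 1, with 4064 cells, was germline-like: 26 genes of the germline list marked it, among them DMC1, a recombinase of meiosis, NANOS3, the RNA helicase gene DDX4 and PIWIL1_1, and it also held 33 markers of S phase and 28 of cilia. Clusters 8 and 13, with 2751 and 2012 cells, were muscle-like, and both expressed MYOD1, TNNT2_1 and RYR2_1. Cluster 13 added the myosin gene Myh6 and the tropomyosin gene TPM1_1. Cluster 29 was also muscle-like, with 8 markers beside 3 heart and mesoderm genes, HAND2_1, FOXF1_1 and ISL1_1. Clusters 27 and 31 were neural-like with 7 and 4 markers, including NEUROG1, PCSK2_1 and CPLX2_1, and cluster 27 also expressed 3 genes of the heart and mesoderm list. Cluster 7 was endostyle-like, marked by NKX2-1_2, FOXQ1, PAX9_1 and FOXA2, transcription factors of the pharynx, and it also held 15 cilia markers. Clusters 11, 16 and 21 were ciliated-like with 20, 22 and 10 cilia markers. Clusters 17 and 45 were phagocyte-like, with the lysosomal genes LAMP1_1, NPC2_1 and ACP5_4 among their markers.

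Circulating cells differed from buds in 5760 of 17816 tested genes, with 2990 higher and 2770 lower in the blood. NHLRC4 (Boschl.Bs4.g5642) showed the largest named rise, a log2 fold change of 12.80 ± 0.78 (standard error, here and below). Its level was 1174 ± 1341 CPM (counts scaled to a common library total; SD, n = 2) in circulating libraries and 0.271 ± 0.195 CPM (SD, n = 8) in buds, with 2122 CPM at circulating stage A1 and 226 at B2. PXMP2_1 rose by 6.18 ± 0.68 to 70.4 CPM, and the ADP-ribosylation factor gene ARF1_4 rose by 5.20 ± 0.47 to 195 CPM. The extracellular integrin ligand gene EDIL3_1 (Boschl.Bs2.g2962) showed the largest named fall, a log2 fold change of -11.33 ± 0.61, from 332 ± 70.4 CPM in buds to 0.0977 CPM in blood. The transcription factor gene EBF1 fell from 59.4 to 0.173 CPM (-8.11 ± 0.89), and H1F0, a linker histone gene, fell from 737 to 1.27 CPM.

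**Figure D1:**
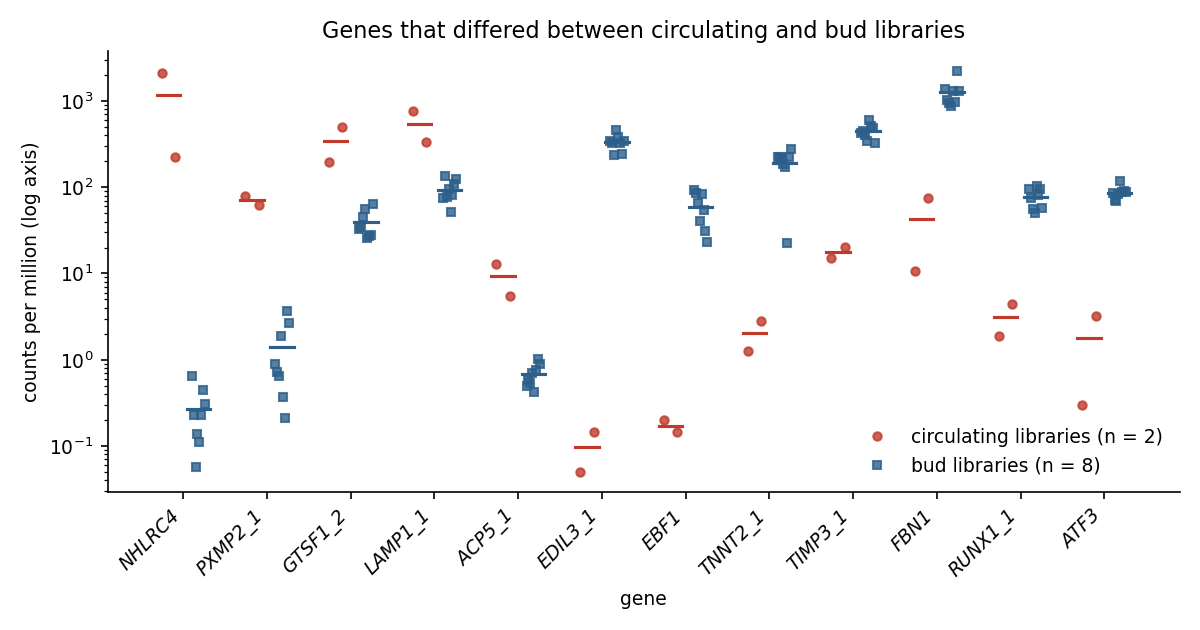
CPM on a log axis for 12 genes, with a point per library (circles, circulating, n = 2; squares, bud, n = 8) and a line at the mean of each group. NHLRC4 had a mean of 1174 CPM in blood and 0.271 CPM in buds, and EDIL3_1 a mean of 0.0977 CPM in blood and 332 CPM in buds.

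Patterning, matrix, muscle and endostyle genes were the lists called lower in the blood by camera, none of them with an estimated correlation. Of 46 tested bud patterning genes 30 fell and 6 rose, the same counts adjusted over the list alone, and RUNX1_1 (-4.28 ± 0.39), also a member of the blood cell and immune list, and the Hedgehog receptor gene PTCH1_1 (-3.07 ± 0.29) were among those that fell. The list as a whole was lower than other genes (camera, adjusted p = 7.64e-08), with adjusted p = 0.183 with an estimated correlation. Of 36 vessel and extracellular matrix genes 21 fell and 3 rose (23 and 3 adjusted over the list alone). The fibrillin gene FBN1 fell from 1252 to 43.1 CPM (-4.63 ± 0.62) and the metalloproteinase inhibitor gene TIMP3_1 from 444 to 17.7 CPM (-4.31 ± 0.37). That list had adjusted p = 1.82e-06, and adjusted p = 0.438 with an estimated correlation. Of 21 muscle genes 8 fell (9 adjusted over the list alone), including the troponin gene TNNT2_1 (-6.25 ± 0.89), at adjusted p = 0.00497, with adjusted p = 0.438 with an estimated correlation. Of 52 endostyle and pharynx genes 10 fell and 2 rose (9 and 1 adjusted over the list alone), a share of falls near that of all genes (2770 of 17816). Among those that fell were PAX9_1 (-6.14 ± 0.85) and FOXA2 (-4.53 ± 0.75). That list had a camera adjusted p of 0.035, and adjusted p = 0.618 with an estimated correlation. Most of its members are copies of SLC5A8.

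Ribosomal protein genes were higher in the blood as a list, with a median log2 fold change of 0.44. Of 67 members 7 were raised and none lowered (6 adjusted over the list alone), a smaller raised share than among all genes (2990 of 17816). RPS21_1 rose from 4046 to 8479 CPM (1.41 ± 0.28) and RPL7 by 1.11 ± 0.29. The list had adjusted p = 0.00497, and adjusted p = 0.977 with an estimated correlation. These 5 lists were the only calls by camera among 19 tested, and none held with an estimated correlation, while fry, which asks only whether a list moves on balance 1 way, called 8.

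The other lists were not called. Phagocyte and lysosome genes split, with 6 of 31 raised and 7 lowered (6 and 8 adjusted over the list alone; adjusted p = 0.839): the acid phosphatase gene ACP5_1 rose by 4.25 ± 0.40 and LAMP1_1 from 93.2 to 547 CPM (3.02 ± 0.36), while the scavenger receptor gene STAB2_1 fell by 2.92 on the log2 scale. Of 63 blood cell and immune genes 9 rose and 18 fell (9 and 20 adjusted over the list alone; adjusted p = 0.295), with the ficolin gene FCN2_14 up by 4.53 ± 0.39 and MASP1_12 at -3.61 ± 0.33. Of 35 germline genes 4 rose and 4 fell (4 and 3 adjusted over the list alone; adjusted p = 0.837). GTSF1_2, a piRNA pathway gene, rose from 39.2 to 348 CPM (3.41 ± 0.35) and SYCP3_3 of the synaptonemal complex stood at -5.10 ± 1.08. That list had a median of 0.35 and a mean of 0.12, opposite in sign to the direction of its test. TDRD5_1 and the kinetochore gene NUF2_1 rose by 2.49 ± 0.62 and 6.22 ± 0.94, but without the circulating stage B2 library their log2 fold changes were -0.12 and -1.40. Of 26 stemness and dedifferentiation genes 4 rose and 11 fell (4 and 13 adjusted over the list alone; adjusted p = 0.148), with ALDH1A1_2 at 2.89 ± 0.29 and KLF5_2 at -6.60 ± 0.99. Apoptosis genes had 12 of 51 raised and 6 lowered, the same adjusted over the list alone (adjusted p = 0.299). In digestion 4 of 27 rose and 7 fell (4 and 8 adjusted over the list alone; adjusted p = 0.113), and TMPRSS15_8, named for enteropeptidase, fell from 70.2 to 0.87 CPM.

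Of 17 dissociation stress genes 3 rose and 5 fell, the same adjusted over the list alone (adjusted p = 0.528). ATF3, a stress-induced transcription factor, was lower in the blood (1.77 against 86.3 CPM, -5.38 ± 0.64). The bud cells had been trypsinised, but whether this set the difference was not tested. In the neural list 4 of 9 fell, the same adjusted over the list alone (adjusted p = 0.239), with CPLX2_1 at -5.24 ± 0.91. Of 7 epidermis and tunic genes 2 fell, also 2 adjusted over the list alone (adjusted p = 0.154), and GRHL2_1 stood at -1.24 ± 0.29. Cilia genes had 3 of 50 raised and 2 lowered (3 and 1 adjusted over the list alone; adjusted p = 0.598), with the dynein gene DNAH6 up by 2.40 ± 0.34. For mitosis 7 of 46 genes rose and 1 fell (5 and 1 adjusted over the list alone; adjusted p = 0.578), among them RACGAP1_1 (1.83 ± 0.29). None of 39 S phase genes passed, with 0 also adjusted over the list alone (adjusted p = 0.924), and their median was -0.13 against a mean of 0.02. For oxidative phosphorylation 2 of 40 rose (1 adjusted over the list alone; adjusted p = 0.333), and 2 of 26 translation and nucleolus genes rose (0 adjusted over the list alone; adjusted p = 0.924), against a median of -0.10.

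Material could not be separated from fixation, genotype, sorting or the kind of matrix deposited, since each differed between the same libraries. With bud stages A1 and B2 alone the count was 2116 genes, 879 higher and 1237 lower, and 18 of 85 named genes no longer passed.

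Across the stage order A1 to C2, 2010 of 17285 tested genes followed a slope in the 7 libraries with primary and secondary buds, with 785 rising and 1225 falling. The secreted phospholipase gene PLA2G5_1 (Boschl.Bs5.g6337) rose by 0.90 ± 0.07 log2 units per stage step, from 9.88 CPM at A1 to 268 CPM at C2. FABP6_1, of the fatty acid binding family, rose by 0.97 ± 0.18 (2.22 to 74.7 CPM) and the chemokine receptor gene CCR4 by 0.79 ± 0.14 (5.97 to 161 CPM). WBSCR27_10 had a slope of -1.07 ± 0.17, from 782 to 18.8 CPM, and the histone gene HIST1H3D_2 a slope of -0.88 ± 0.22. GLI2_1, a transcription factor of Hedgehog signalling, stood at -0.65 ± 0.09 per step (83.4 to 6.64 CPM), the nuclear lamin gene LMNB1 at -0.61 ± 0.09 (143 to 12.4 CPM), and the glycyl-tRNA synthetase gene GARS1_1 at -0.76 ± 0.10.

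**Figure D2:**
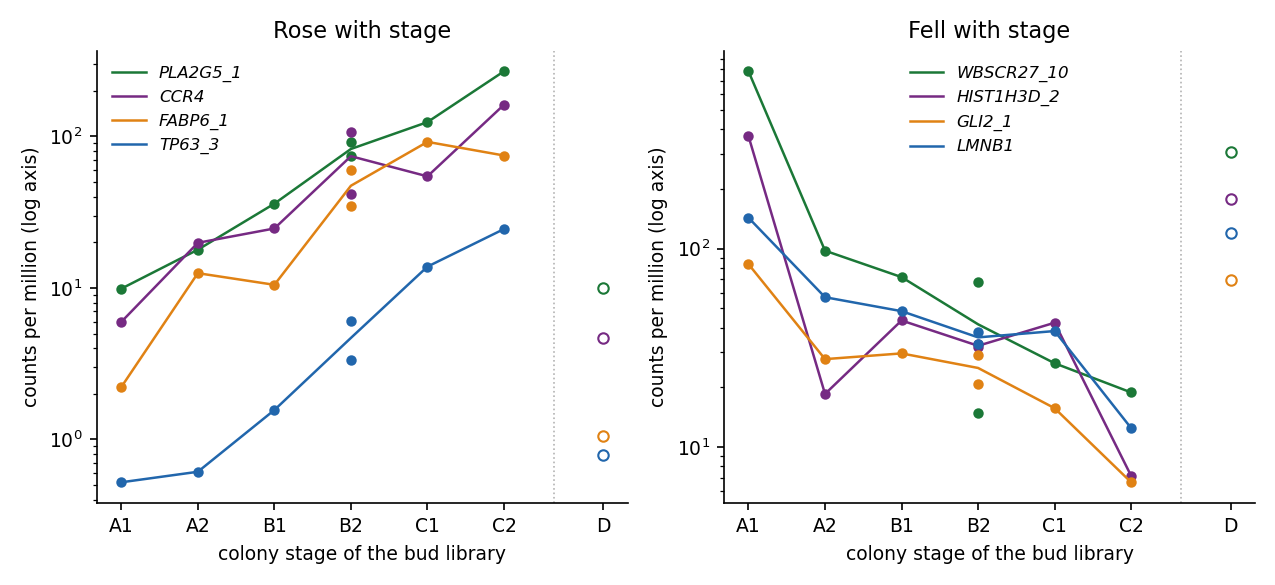
CPM on a log axis against colony stage for 4 genes that rose and 4 that fell, with a point per library, a line through the stage means and open circles for stage D, which was not in the fit. PLA2G5_1 rose from 9.88 CPM at A1 to 268 CPM at C2, and WBSCR27_10 fell from 782 to 18.8 CPM.

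The germline-like cluster 1, with 28 cilia and 26 germline markers, held a larger share of cells at C1 (13.2%) and C2 (5.08%) than at A1 (1.80%), which bears on both of these lists. Cilia genes rose along the order, 9 of 50 with none falling (17 and 0 adjusted over the list alone), among them the dynein genes DNAH5_1 (0.80 ± 0.16) and DNAH9_1 (0.73 ± 0.15) and the tektin gene TEKT3 (0.75 ± 0.13). The list had adjusted p = 6.12e-06, and adjusted p = 0.757 with an estimated correlation. All but 1 of 67 ribosomal protein genes had a negative slope, although none passed alone (0 adjusted over the list alone); the median was -0.20, at adjusted p = 2.65e-06, with adjusted p = 0.854 with an estimated correlation. Translation and nucleolus genes fell in 4 of 26 cases (7 adjusted over the list alone), with the initiation factor gene EIF3B_1 at -0.51 ± 0.10 and the nucleolar gene NOLC1 at -0.42 ± 0.07, at adjusted p = 0.00218, with adjusted p = 0.84 with an estimated correlation. Of 35 germline genes 3 rose and 1 fell (7 and 2 adjusted over the list alone), with SOX8_1 at 0.41 ± 0.11 and FOXL2_3 at -1.17 ± 0.14, at adjusted p = 0.00174, with adjusted p = 0.854 with an estimated correlation. Endostyle and pharynx genes rose in 6 of 50 cases and fell in 4 (12 and 4 adjusted over the list alone), at adjusted p = 0.00218, with adjusted p = 0.757 with an estimated correlation; the risers SLC5A8_62, SLC5A8_78 and SLC5A8_22 are transporter copies, and the thyroid factor gene Pax8_1 fell by 0.36 per step. Digestive genes rose in 5 of 27 cases and fell in 1 (5 and 1 adjusted over the list alone), with the carboxypeptidase gene CPA1_5 at 0.93 ± 0.15, at adjusted p = 0.045, with adjusted p = 0.757 with an estimated correlation. Fry called none of the 19 lists.

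Among lists not called, 5 of 44 bud patterning genes fell and 1 rose (5 and 1 adjusted over the list alone; adjusted p = 0.379), with the Notch ligand gene JAG2_2 at -0.57 ± 0.09 and TBX1_1 at -0.34 ± 0.06. Of 46 mitosis genes 7 fell and 1 rose (12 and 2 adjusted over the list alone; adjusted p = 0.0573), with TPX2 at -0.34 ± 0.07, and of 39 S phase genes 1 rose and 1 fell, CCNE1_1 (0.28 ± 0.06) and FEN1 (-0.38 ± 0.09), as adjusted over the list alone (adjusted p = 0.772). For stemness and dedifferentiation 3 of 25 rose and 2 fell (4 and 5 adjusted over the list alone; adjusted p = 0.768), with the chromatin gene HMGA2 at -0.87 ± 0.09 and YAP1 at -0.56 ± 0.10. In the epidermis and tunic list TP63_3 rose from 0.522 to 24.4 CPM (1.16 ± 0.11) while TP63_4 fell from 29.8 to 3.57 CPM, 1 of 7 each way (2 and 1 adjusted over the list alone; adjusted p = 0.768), with a median of -0.03 and a mean of 0.05. Muscle genes rose in 3 of 21 cases and fell in 1 (5 and 1 adjusted over the list alone; adjusted p = 0.0991), with MYBPC3_1 at 0.46 ± 0.10 and SMYD1_1 at -0.37 ± 0.08. Of 9 neural genes 1 rose and 3 fell (3 and 4 adjusted over the list alone; adjusted p = 0.768), with NEUROG1 at -0.36 ± 0.08; the median was 0.05 and the mean -0.10. Immune genes had 3 of 59 raised and 5 lowered, also adjusted over the list alone (adjusted p = 0.913), with IRF8_9 at -0.36 ± 0.08, and phagocyte genes 2 of 31 raised, also adjusted over the list alone (adjusted p = 0.0826). Apoptosis genes had 3 of 47 raised and 4 lowered (3 and 5 adjusted over the list alone; adjusted p = 0.389), with CASP9 at -0.54 ± 0.10. In the vessel and matrix list 1 of 36 rose and 1 fell, as adjusted over the list alone (adjusted p = 0.768), with the fibronectin gene FN1_3 at 0.31 ± 0.08. HSPA5 alone rose among 16 stress genes (1 up and 3 down adjusted over the list alone; adjusted p = 0.0826), and COX5B_1 alone fell among 40 genes of oxidative phosphorylation (also 1 adjusted over the list alone; adjusted p = 0.78).

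With library code as a block, a fit with 1 residual degree of freedom that rests on the 3 libraries of code ML232, edgeR called 0 genes, with 2837 at an unadjusted p under 0.05. In that fit 68 of the 74 named genes kept the sign of their slope, and HIST1H3D_2, SNAP25_1, Pax8_1, FEN1, TPX2 and EIF4G1 did not. The stage A1 library carried much of this trend: without it 76 genes passed, 61 rising and 15 falling, and 9 of the 74 named genes kept their call. The count was 674 without C2, 1331 without B1, 370 with the stages of both conflictingly labelled libraries exchanged and 634 without the 3 libraries of code ML232. Within these 3 libraries, 84.4% of the 634 genes moved from A2 to B2 in the direction of their slope, and 66.9% with the stages exchanged.

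By stage letter, the 2 C libraries exceeded the 2 A libraries in 47 genes and lay below them in 7, of 18244 tested. BAI1_1, an adhesion receptor gene, rose from 7.42 ± 4.3 to 70.5 ± 0.53 CPM (SD, n = 2 each), PLAC8_4 from 1.35 to 25.1 CPM and the secreted phospholipase gene PLA2G5_1 from 13.9 to 196 CPM. The retinaldehyde dehydrogenase gene ALDH1A1_3, a member of both the patterning and the stemness lists, rose from 19.3 to 82 CPM. MLLT3_1 fell from 35.9 to 9.69 CPM and the homeobox gene NKX6-2_1 from 24.3 to 6.85 CPM. Between C and B, 4 genes were higher in C and none lower, and 1573 had an unadjusted p under 0.05. The only named gene of the 4, FIBCD1_23, rose by 4.23 ± 0.52, and it was chosen after its values were seen. No gene passed between B and A with edgeR, where 2067 had an unadjusted p under 0.05 and DESeq2 called 433, 284 higher and 149 lower. DESeq2 called 205 genes between C and B, 167 higher, and 1505 between C and A, 819 higher.

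Germline genes had the largest median difference of the lists called between the letters, 1.15 higher in B than in A (adjusted p = 8.25e-14, and adjusted p = 0.718 with an estimated correlation) and 1.35 higher in C than in A (adjusted p = 9.89e-08, and adjusted p = 0.613 with an estimated correlation). None of the 35 members passed alone, but 17 were higher and 1 lower in B, and 16 higher and 2 lower in C, adjusted over the list alone. Within code ML232 the B to A median was 0.83 and 31 of 35 were higher in B. The libraries of this code are also in the letter fit, so values within ML232, here and below, are not a separate check. Cilia genes were higher in B than in A by a median of 0.40 (0 of 50 passed, also 0 adjusted over the list alone; adjusted p = 9.44e-06, and adjusted p = 0.718 with an estimated correlation) and in C than in A by 0.75 (1 passed, and 7 adjusted over the list alone; adjusted p = 1.33e-07, and adjusted p = 0.613 with an estimated correlation). Within ML232, 44 of 50 were higher in B, with a median of 0.27. S phase genes were higher in B than in A by 0.33 (adjusted p = 0.00375, and adjusted p = 0.747 with an estimated correlation) and oxidative phosphorylation genes by 0.25 (adjusted p = 0.00531, and adjusted p = 0.772 with an estimated correlation), with medians of 0.29 and 0.13 within ML232. Stress genes lay lower in B, by -0.59 (adjusted p = 0.00676, and adjusted p = 0.718 with an estimated correlation), but their median was -0.06 within ML232. Muscle (0.19), stemness (0.19) and apoptosis (-0.27) genes had adjusted p = 0.0463 each, and adjusted p = 0.718 with an estimated correlation; their medians within ML232 were -0.18, 0.01 and -0.06.

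Between C and B, all 67 ribosomal protein genes lay lower in C, by a median of -0.64 (adjusted p = 4.34e-14, and adjusted p = 0.67 with an estimated correlation), as did translation (-0.58; adjusted p = 4.59e-08, and adjusted p = 0.556 with an estimated correlation) and mitosis genes (-0.35; adjusted p = 5.83e-06, and adjusted p = 0.54 with an estimated correlation). The S phase median was -0.36 (adjusted p = 0.000114, and adjusted p = 0.693 with an estimated correlation), that of oxidative phosphorylation -0.33 (adjusted p = 0.000313, and adjusted p = 0.693 with an estimated correlation) and that of patterning -0.42 (adjusted p = 0.00151, and adjusted p = 0.54 with an estimated correlation). Cilia (0.26; adjusted p = 0.00191, and adjusted p = 0.693 with an estimated correlation), endostyle (0.34; adjusted p = 0.00282, and adjusted p = 0.67 with an estimated correlation), digestive (0.35; adjusted p = 0.00282, and adjusted p = 0.637 with an estimated correlation) and phagocyte genes (0.22; adjusted p = 0.0166, and adjusted p = 0.67 with an estimated correlation) lay higher in C. No member of these 10 lists passed over all genes, and adjusted over the list alone 2 cilia, 1 endostyle, 2 digestive and 2 phagocyte genes were higher. Against A, C was lower for ribosomal protein (-0.66; adjusted p = 3.98e-07, and adjusted p = 0.697 with an estimated correlation) and translation genes (-0.58; adjusted p = 0.000132, and adjusted p = 0.613 with an estimated correlation). It was higher for endostyle (0.87; adjusted p = 0.000648, and adjusted p = 0.613 with an estimated correlation) and digestive genes (0.42; adjusted p = 0.0276, and adjusted p = 0.613 with an estimated correlation). Median, mean and test differed in sign for some uncalled lists, namely digestion, epidermis, vessels, mitosis and ribosomal proteins between B and A, epidermis and vessels between C and B, and neural, epidermis and immune genes between C and A.

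These letter results rested on few libraries. With doublets kept, edgeR called 0 genes between C and A (3716 at an unadjusted p under 0.05), and all 14 named genes lost their call. Between C and A the count was 0 without A1 or C2, 1 without the first B2 library, 21 without D, 40 without A2 (16 higher and 24 lower), 100 without C1, 122 without the second B2 library and 209 without B1, and between C and B it was 0 without A1, B1 or C2, 9 without A2 and 10 without the second B2 library. Between B and A it was 11 without A2, 3 without B1 and 2 without the first B2 library.

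The muscle-like cluster 8 lost share along the stage order, from 5.90% of cells at A1 and 5.77% at A2 to 3.84% at B1, 2.68% and 1.44% at B2, 0.623% at C1 and 0.222% at C2. The A1 share had an exact Clopper-Pearson 95% interval of 5.43% to 6.38% and the C2 share 0.101% to 0.421%, intervals which cover counting error only. Its markers included MYOD1, TNNT2_1 and the muscle ligase gene TRIM63_1, and its share in stage D was 6.17%. Spearman's rho with stage was -0.991 over 7 libraries (two-sided exact permutation p = 0.000794, adjusted 0.0421 over 53 clusters) and Pearson's r was -0.966 (adjusted permutation p = 0.021). Without A1 and C2, r was -0.974; C2 was taken in place of A2, which lies as far from the median stage. Within code ML232 the share also dropped, by 4.33 percentage points. Its 3 libraries are among the 7 that gave rho, so this is not a separate check. No cluster was called with the conflicting stages exchanged or with genes centred per library.

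**Figure D3:**
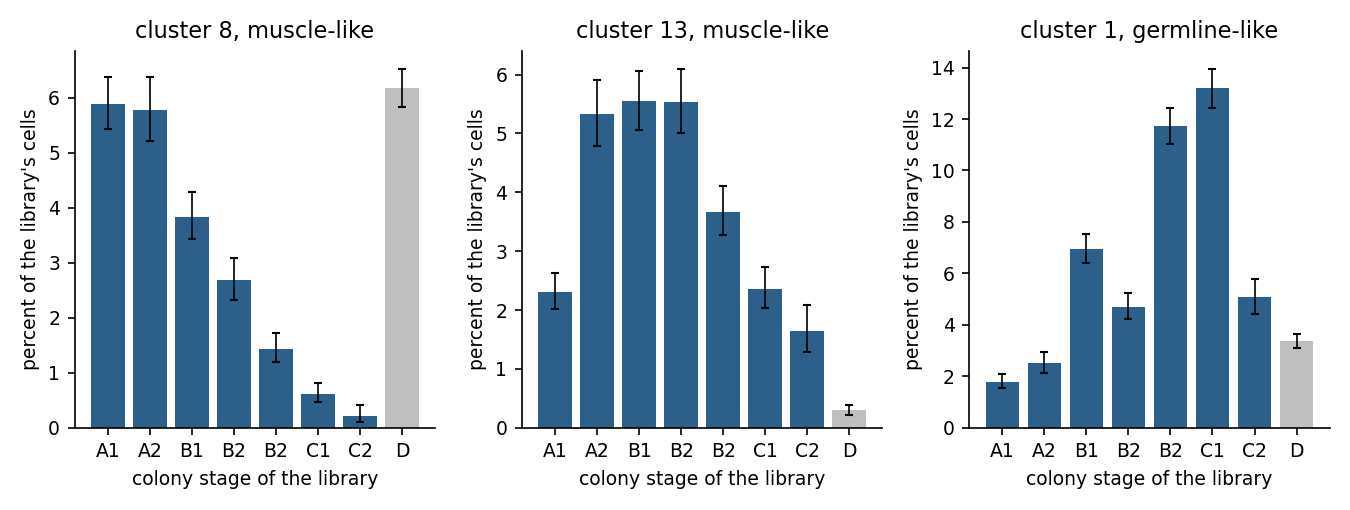
Percent of each library's cells in bud clusters 8, 13 and 1 by colony stage, with exact 95% binomial intervals as bars and stage D in grey. Cluster 8 went from 5.90% at A1 to 0.222% at C2 and was at 6.17% at D.

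No other cluster passed by rho. Cluster 8 included, 12 clusters had an unadjusted permutation p under 0.05 and Pearson's r called 5. Muscle-like cluster 13 held 2.30% at A1, 5.33% to 5.55% at A2 and B1, and 1.65% at C2 (rho -0.324; exact permutation p = 0.482). The germline-like cluster 1 held 1.80% at A1, 11.7% in a B2 library, 13.2% at C1 and 5.08% at C2 (rho 0.667, exact permutation p = 0.117). The libraries of stage B2 by the stage field differed, 4.70% against 11.7%. Cluster 24, marked by CCR4 and PLA2G5_1, went from 0.186% at A1 to 3.16% at C2 (rho 0.937; exact permutation p = 0.00476, adjusted 0.0841; r 0.929, adjusted permutation p = 0.0421). Cluster 15 went from 1.58% to 4.88% with the same rho (r 0.790, adjusted permutation p = 0.155). Libraries had been sorted for single cells and differed in depth, which can set such shares. With a library left out, rho of cluster 8 stayed between -1 and -0.986. Without the first B2 library 5 clusters were called, and 0 without any other, where the smallest p was 0.00278 or 0.00556 and a lone cluster of 53 could not pass.

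Within clusters, genes followed the stage order in all 25 clusters with at least 20 cells per library. There were 9408 calls over 142981 tests, 4913 rising and 4495 falling. They fell on 4705 genes, 201 of which were called in more than 1 direction. The block on library code was not fitted within clusters, so stage and code stay confounded there too. The ciliated-like cluster 11 had 1852 calls, the endostyle-like cluster 7 had 1337 and the germline-like cluster 1 had 728. Muscle-like cluster 13 had 431 and neural-like cluster 27 had 386. With a library left out these fell to as few as 788 in cluster 11 and 131 in cluster 13, both without C2, and to 179 in cluster 1 and 63 in cluster 27, both without A1. Cluster 7 had 338 rising and 188 falling without A1. With the conflicting stages exchanged they were 769, 513, 471, 160 and 131 in clusters 11, 7, 1, 13 and 27. GSPT1, a translation termination factor gene, fell in 13 clusters, GARS1_1, LMNB1 and the initiation factor gene EIF3B_1 in 12 each, and NOLC1 in 10. FABP6_1 rose in 14 clusters and the germline genes PIWIL1_1 and DDX4 in 11 and 10. DDX4 stood at 1635 CPM in cluster 1, its highest, and at 13.2 CPM in the median cluster, while GSPT1 had 113 and 51.9 CPM. The genes named here were chosen after their values were seen, for the number of clusters they moved in. The calls were 4299 without A1 (2944 rising and 1355 falling), 4090 without C2, 6142 without A2 and 4238 with the conflicting stages exchanged. Clusters with a call numbered 21 without C2, 24 without A2, B1 or C1, and 23 with the exchange.

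In the blood, a germline-like cluster was found almost only in the stage B2 library. With 1 library per stage, from different numbers of pooled clones, it may mark the library or its clones as well as a cell type. Circulating cluster 12 had 30 germline markers such as DDX4 and TDRD9 and 44 cilia markers such as DNAI2, beside 30 of S phase and 25 of mitosis. Its profile was mixed, with also 14 vessel and matrix, 10 blood cell and immune and 6 muscle markers. The cluster held 110 of 873 barcodes at B2 (12.6%, exact 95% interval 10.5% to 15.0%). At A1 it held 0 of 1329, which allows a share of up to 0.226% by a floor of 3 counts. Over all clustered barcodes, whatever their UMI minimum, it held 225 of 4682 at B2 and 3 of 3488 at A1. Cluster 32 held 0 of 1329 barcodes at A1 and 28 of 873 at B2 (3.21%). Phagocyte-like clusters were present at both stages: cluster 7 held 9.48% and 10.1%, and cluster 20, marked by MRC1_7, held 6.17% at A1 and 2.06% at B2. Cluster 8, with 4 phagocyte markers, held 6.70% and 8.36%. Cluster 5, with 22 S phase and 13 mitosis markers including MKI67_1, held 18.8% at A1 and 16.2% at B2. The UMI minimum was 3844 at A1 and 7622 at B2, and 15.1% of A1 barcodes were removed as doublets against 4.72% at B2, where another rule was used, so both steps can set these shares.

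**Figure D4:**
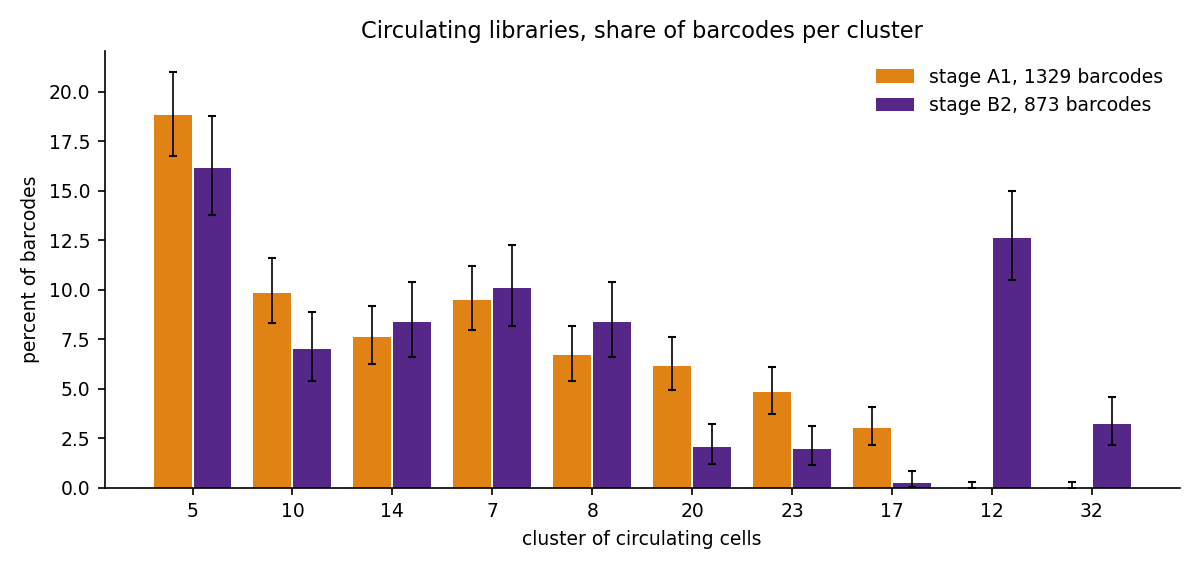
Percent of circulating barcodes past the UMI minimum in 10 clusters at stage A1 (1329 barcodes) and B2 (873 barcodes), with exact 95% binomial intervals. Cluster 12 held 0 barcodes at A1 and 12.6% at B2, and clusters 7 and 8 held 6.70% to 10.1% at both stages.

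With 1 library per stage, no test was possible for blood genes. The scavenger receptor gene LRP2_3 had 579 CPM at B2 and 3 counts, or 0.150 CPM (Poisson 95% interval 0.0310 to 0.439), at A1. KLHL13_3 had 395 CPM at B2 and no count at A1, at least 2626-fold higher against a floor of 3 counts, but the ratio was 179.7 without barcodes over 100000 UMIs and 73.7 with doublets kept. The cadherin gene FAT3_7 had 1208 against 0.801 CPM. These differences depended on the barcodes used: the LRP2_3 ratio of 3853 was 461 without barcodes over 100000 UMIs and 56.5 with doublets kept, and that of FAT3_7 fell from 1507 to 141 and 76.3. The 3 barcodes over 100000 UMIs at A1 had been called doublets. Higher at A1 were GSTO1_2, a glutathione transferase gene (143 against 0.690 CPM), and MFGE8_11 (1800 against 97.1 CPM). The MFGE8_11 ratio of B2 to A1 was 0.0539, but 0.0864 without barcodes over 100000 UMIs and 0.136 with equal weight per cell. The meprin genes mep1b_4 (394 against 14.1 CPM) and MEP1B_7 (79.8 against 3.89 CPM) were also higher at A1. With all barcodes of at least 500 UMIs, however, the meprin ratios of B2 to A1 were 0.726 and 1.13. As list totals, germline genes had 284 CPM at A1 (617 with doublets kept) and 2915 at B2 (1670 without the large barcodes). Cilia genes had 251 CPM at A1 and 936 at B2 (689 without the large barcodes). Phagocyte genes had 2135 CPM at A1 and 1164 at B2, but 1605 at B2 without the large barcodes, where the ratio of B2 to A1 went from 0.545 to 0.752. The pigment cell and phenoloxidase list matched only 3 features, with 838 CPM at A1 and 188 at B2 (293 without the large barcodes). The heart and mesoderm list matched 4, with 2.55 CPM at A1 (13.7 with doublets kept) and 63.7 at B2 (45.3 without the large barcodes).

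The stage D library, secondary buds only, stood below all 7 other bud libraries in some contractile genes, though MYH7B_4, a myosin gene, was highest there (2.51 CPM, 1.84 times the next library). The tropomyosin gene TPM1_1 had 7.72 CPM against 112 to 360.2 in the others, Myh6 had 2.84 against 26.8 to 84.5, and TNNT2_1 had 22.6 against 172 to 275. Muscle-like cluster 13 held 0.299% of its cells (exact 95% interval 0.225% to 0.389%). Neural-like cluster 27 held 0.125% against 1.05% to 2.13% elsewhere. Muscle-like cluster 8 and neural-like cluster 31 had their highest shares at D, 6.17% and 1.73%, and muscle-like cluster 29 held 1.31% there against a highest of 1.36% at A2. Above all others at D were C1QTNF4 (123 CPM, 3.46 times the next library), EIF4EBP2 (6.20 CPM, 4.81 times) and CDX2_1, a homeobox gene of the gut (1.52 CPM, 2.27 times). Named genes were also counted where a library's Poisson 95% interval cleared those of all others, with at least 50 counts in the higher library. By this rule D lay above the others for 206 genes and below for 254. A1 did so for 731 and 659, and C2 for 1239 and 595. With 1 library and another tissue mix, these values carry no test.

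Both stage B2 libraries correlated at 0.974 in log2 CPM across 19814 genes, and this ranked number 6 of 28 pairs of bud libraries. The closest pair was A1 with D (0.988), which share a library code, followed by B1 with the second B2 library (0.987), which also share one. The lowest was A1 with C2, at 0.912. In cluster shares the B2 pair ranked number 11. The germline-like cluster 1 and muscle-like cluster 8 differed between the B2 libraries, 4.70% against 11.7% and 2.68% against 1.44%. This pair follows the stage field, and the second B2 library is 1 of the 2 with conflicting labels. By title, the first B2 library would pair with the library grouped here as B1. That pair correlated at 0.970, number 11, and ranked number 6 in cluster shares. Its shares were 4.70% against 6.95% in cluster 1 and 2.68% against 3.84% in cluster 8.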

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

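The tests of library code alone and of several cells per droplet were chosen after their results were seen, and the labelling rule of the centring test was altered after its value was seen. Of 60 groups of 8 bud libraries (7 library measures and 53 cluster shares), 8 held a library far from the others, where chance marks about 1 in 20. The stage D library had 129221321 UMIs in total. Stage A1 had 19.6% of its cells in cluster 4, stage A2 had 2.90% in cluster 32 and 1.08% in cluster 40, stage C2 had 4.17% in cluster 23, 3.30% in cluster 25 and 3.48% in cluster 36, and the first B2 library had 0.817% in cluster 45, which was phagocyte-like. Clusters 4 and 40 were of low depth. Circulating barcodes below the UMI minimum also carried structure: 30.2% of them at stage A1 fell in cluster 1 (GLIPR2, ITLN1_6, SLC5A8_1) and 17.7% in cluster 3 (col6a6_4, CHST9_3, ITLN1_25), and at stage B2 25.6% fell in cluster 0 (FIBCD1_7, LGALS9_1, SLC5A8_68) and 16.0% in cluster 2 (DCDC2_1, LRP5L_16, OVCH1_7).

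Stage A1 and stage D buds, which share library code ML245, had the highest shares in a common set of clusters. In 12 clusters, the muscle-like cluster 8 and the neural-like cluster 31 among them, both lay above all 6 other libraries. These clusters held 38.8% of A1 and 47.3% of D cells against at most 16.4% elsewhere. Some were well filled by other libraries too, such as cluster 8 with 5.77% of A2 cells against 5.90% of A1 cells. The stage A2 library, of another code, was the highest of the 6 in 8 of the 12 clusters. The clusters were picked from the same shares, and this count rests on the A2 library only. It therefore cannot decide whether library code alone set these clusters. A shift of all ML245 cells stays open: with genes centred per library the mean difference in shares was 60.1 percentage points, within the largest among the 6 others (65.2), which met the bound written beforehand for a shift, but centring did not lower it from 52.0, so it was read as undecided. A stage difference, with primary and secondary buds at A1 and secondary buds only at D, was not separable from the code.

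Of the genes that followed the stage order in 10 or more clusters, 28 rose and 28 fell. Rising genes such as DDX4 and PIWIL1_1 were concentrated, with a median ratio of 109 between the highest and the median cluster. Free RNA from a few cell types in the droplets would give such a value. The ratios went down to 4.36, however, and Boschl.Bs2.g2392, which rose in 24 clusters, had 5.58. Only 4 of the 28 had their highest level in the germline-like cluster 1, so free RNA stays open for the rising genes. For falling genes such as GSPT1, LMNB1 and EIF3B_1 the median ratio was 2.63, and the highest was 14.7. With levels pooled over all libraries, the median argues against free RNA from a few cell types as the source of this set. Free RNA of genes expressed in many cell types would also give low ratios, so the test cannot exclude it. A change shared by many cell types, or a difference between library codes, also stays open for the falling genes.

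In the circulating stage B2 library, 38 barcodes exceeded 100000 UMIs, the largest with 1289456, and held 38.9% of its kept UMIs. They carried 9886 CPM of mitosis genes against 2645 in the other barcodes, 4869 against 1670 CPM of germline genes and 473 against 1605 CPM of phagocyte genes, and detected a median of 8992 genes. Over 5 times the level of their highest cluster lay 18 of 1705 named genes, short of the 20 set to exclude several clustered cells per droplet. That level is pooled over a whole cluster and single cells can lie above it, so the count cannot decide. Clumps and large cells, such as germ cells, cannot be told apart here, and no biological explanation was tested.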

How the results depend on the processing

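Alternatives without low-depth clusters, without large barcodes and without ML232, the block on library code, and the tests of chance order and of the titles, were chosen after the results were seen. Of the named genes between circulating and bud libraries, 905 of 935 gene and setting pairs kept direction and call and 30 lost the call; for the slope 566 of 884 kept both, 312 lost the call and 6 reversed. The count between materials was 2116 with bud stages A1 and B2 only, with fewer samples, and 4740 to 5868 with a library left out; leaving out a circulating library moved the median of all genes by -0.13 (A1) or -0.21 (B2). Between B and A it was 433 with DESeq2, 3 with equal weight per cell, 2 with library code as a block and 0 to 11 with a library left out. Between C and B it was 205 with DESeq2, 19 with no filter, 12 with equal weight and 0 to 10 with a library left out. Between C and A it was 1505 with DESeq2, 219 (146 up, 73 down) with no filter, 22 with at least 1000 UMIs, 0 with doublets kept (3716 at an unadjusted p under 0.05), 109 (80 up, 29 down) with equal weight, 18 without low-depth clusters, 21 with D out of the fit, and 0 to 209 with a library left out. Without C1 the median of all genes moved by -0.14 between C and B. The slope count was 3447 with DESeq2, 1137 with equal weight, 370 with B1 and B2 exchanged, 0 with D last (511 at an unadjusted p under 0.05), 74 by letter order, 634 without ML232, 0 with library code as a block (2837 at an unadjusted p under 0.05), and 76 to 2503 with a library left out. Over free orders of the 7 libraries, the real order gave 2010 genes, the only 1 of 100 to reach it, against 50 for the highest other. These orders ignore the shared codes, so they cannot tell stage order from library code or from the weight of the A1 library. The fall to 370 with the exchange does not settle which label names the right stage. Clusters whose share followed stage numbered 0 with centring, 2 with doublets kept, 0 with B1 and B2 exchanged, 0 with D last, and 0 to 5 with a library left out. Calls within clusters were 4238 with the exchange and 4090 to 9080 with a library left out. List calls of 5, 8, 10, 6 and 6 in the 5 gene comparisons became 0 with an estimated correlation. With the block on code the slopes of HIST1H3D_2 (0.40), SNAP25_1 (0.0691), Pax8_1 (0.11), FEN1 (0.0385), TPX2 (0.10) and EIF4G1 (0.0359) reversed. Other reversed values were the muscle median between B and A within ML232 (-0.18), TDRD5_1 (-0.12 to 3.33) and NUF2_1 (-1.40 to 7.17) with a library left out, and the MEP1B_7 ratio of 1.13 with circulating barcodes from 500 UMIs. Except where fewer samples are named, the cause was not tested. The block shares code ML232 across stages and leaves 1 residual degree of freedom, and stage letter C shares no code with the others. No paired analysis was possible because, by replicate number, the labels number only the libraries titled B2 as replicates, so the groups compared share no such numbers. Depth limits low genes: the median kept cell had 2314 UMIs in the first B2 library and 2994 at C2.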

Other observations

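The test of the stage D position was set before its result was seen. Neural-like cluster 27 combined CPLX2_1, SNAP25_2 and PCSK2_1 with TBX20, ISL1_1 and FOXF1_1 in 780 cells. Cluster 26 had 18 vessel and matrix markers, including the fibronectin gene FN1_4 and the collagen gene COL2A1. Cluster 33, with 5 mitosis markers such as STMN1_1 and TPX2, held 2.07% of A1 cells, 1.92% of D cells and 0 of the cells at C2.

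The place of stage D on the stage order was estimated from the genes with a slope. With slopes from all 7 libraries it lay at 1.57, near A1, and with 76 genes from a fit without A1 at 3.09 (2.76 to 3.404 over resampled genes). The bounds set were a value above 5 if D continues the order after C2 and one below 3 if it does not. Yet C2 itself, of order 6, was placed at 4.79 from the 6 others, and C1, of order 5, at 3.87. A1 itself was placed at 2.86 from the 6 others, against its own order of 1. The estimate thus draws both early and late stages toward the middle, the bounds cannot decide, and the position stays undecided.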
